A study of Homo sapiens with 6 samples.

How the data were processed

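The samples were 6 preparations of total RNA from expanded human Tregs, 3 cultured in medium with IL-2 and 3 with IL-12 and IL-18 added, per the labels' protocols. The cells were sorted by flow cytometry before RNA extraction with a column kit, proteinase K digestion and heating, per the labels' protocols. The deposited values are log2 levels, 1 per gene and sample. The submitters' processing notes name Partek, with no version. The assay platform, background correction and normalization method are not given in the sources used here. Row names mark 6 positive and 8 negative control probes beside 526 genes, as in panels that count hybridised probes directly.

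The values themselves showed part of what was done to them. Anti-logs of the low control values were whole numbers in 100% of cases within a tolerance of 0.1, and high control values were not checked. Anti-logs of gene values under 20 on the deposited scale were whole multiples of 1 step per sample in 100% of cases within the same tolerance. The step was fitted to these same values, so this share is partly built in. Steps were 0.862, 0.758 and 0.945 in media A, B and C and 1.422, 0.726 and 1.073 in treated A, B and C. The gene values thus carry 1 scaling factor per sample and the low control values none, and how the factor was derived is unknown. Dividing by the step gave between 373560 and 598825 counts per sample. Because the deposited unit is log2, tests were made on the log2 values, with no count model. Background per sample was the mean plus 2 SD of the negative controls, brought to the gene scale with the step, and ranged from a log2 level of 3.50 to 4.99. A high background in treated sample A (4.99) means that low genes are measured less precisely there. A value of exactly 0 occurred once in media B and once in media C.

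Genes were kept for testing where the mean over 6 samples reached log2 of 20 (4.32), which left 338 genes and removed 188. Control probes were left out. Housekeeping genes are not marked in the table and were tested. Of the 526 symbols, 515 matched the gene table of current symbols, 8 matched through a synonym and 3 did not match, and all are given as the table has them. Coordinates are not given because the probes' genome build is not stated in the sources used here.

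Differences were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided) between 3 treated and 3 media samples, with Benjamini-Hochberg adjustment over 338 genes and a threshold of 0.05. Log2 differences are treated minus media. The groups share the letters A, B and C, and the design text reads as 3 samples under 2 conditions each. Whether letters pair the samples was checked from the correlation, across genes, of deviations from the group means. Same-letter samples correlated at 0.698 (A), 0.794 (B) and 0.611 (C), and each media sample correlated best with the treated sample of its own letter. The letters were therefore taken to pair the samples, and the fit with the letter as a block is given beside the unblocked fit where it changes a call. The median residual SD was 0.185 with the block and 0.358 without it. The labels do not say whether the letters are donors or repeat cultures, so p-values measure the spread between these samples, which may be partly technical.

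The groups, the unblocked model, the floor, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Of the gene lists, 18 with at least 4 tested members were tested with fry, for a shift in one direction and for change in either direction, and with camera, which compares a list with the other genes, at a preset correlation of 0.01 and with an estimated correlation. The lists covered Treg identity, Tr1, Th1, Th2 and Th17 genes, receptor signalling, cytotoxic, interferon response, coinhibitory, costimulatory, secreted, homing, quiescence, NF-kappaB, T-cell receptor, TGF-beta, antigen processing and apoptosis genes. Apart from the calls described in the report, every list had a fry adjusted p above 0.05 for a shift in one direction and a camera adjusted p above 0.05, with and without the block. Genes were also adjusted over each list alone. The panel holds immune genes, so camera compares a list with other immune genes. Members of a list are not independent of one another.

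Named genes followed a rule. It took the 10 largest rises and 10 largest falls among genes past the threshold whose 3 same-letter differences agreed in sign. Where fewer than 5 passed in a direction, it took the 5 smallest p-values in that direction. It also took a fixed set of 25 genes of Treg, Tr1 and Th1 biology where measured, up to 4 members of each list with the smallest p, and the markers of other cell types with the highest levels. Some genes that the rule names are not reported here. The 3 genes per direction called with the block came under other parts of the rule.

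The gene and list tests were also tested on simulated data: log2 values were drawn for the 338 genes with the real means, letter effects and residual SDs, and 17 genes at each of 2 sizes were changed in each of 50 simulations. For the comparison of IL-12 and IL-18 against media, the unblocked fit recovered 19.2% of changes of 1 and 83.5% of changes of 2 on the log2 scale. The blocked fit recovered 83.3% and 96.9%, with 4.74% false calls on average. A list of interferon genes shifted by 0.5 was called by fry in 4% of unblocked and 48% of blocked simulations and by camera with the preset correlation in 100% of both. The simulated genes were drawn independently within a list, which favours camera. Noise had the blocked fit's residual SD and was equal in all 6 samples, whereas sample weights in the data ran from 0.418 (treated A) to 2.59 (treated C). The recovered and false shares therefore hold for that simpler setting only.

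Alternatives covered the block, housekeeping scaling, median centring, quantile normalization, no floor, a floor of log2 of 50, a pseudocount of 10, no intensity trend, sample weights, camera, and leaving out each sample or pair. A random block, a floor from the negative controls and combinations of the block with other settings were added after seeing the data.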

Results

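Human regulatory T cells (Tregs, the CD4+ T cells that restrain immune responses) were expanded in culture and their immune transcripts were measured on a targeted gene panel. The cells had been isolated by flow cytometry as CD4+CD127lo/− and activated with beads coated with antibodies to CD3 and CD28. Rapamycin, an inhibitor of the kinase mTOR, was present at 100 ng/ml until day 7, IL-2 was given at 300 units/ml from day 2, and the beads were renewed on day 9. A group of 3 cultures received medium with IL-2 alone (media A, B and C), and a group of 3 received IL-12 at 1 ng/ml and IL-18 at 10 ng/ml (A, B and C). The series title speaks of skewing Tregs towards Tr1 cells, a type of regulatory T cell known for IL-10 secretion, and the comparison asks which immune transcripts differ when both cytokines are present. The values cover 526 genes on a log2 scale, of which 338 lay on average above the floor and were tested. Counts recovered from the values totalled 598825, 556010 and 586658 in media A, B and C and 373560, 553763 and 413287 in the treated samples A, B and C. Between 312 and 438 genes per sample exceeded the background set by 8 negative control probes.

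Cells cultured with IL-12 and IL-18 had higher transcript levels of 3 genes of type 1 T-cell responses and lower levels of 3 other genes when each treated sample was compared with the media sample of its own letter. IFNG, which encodes interferon-gamma, rose from a log2 level of 4.31 ± 0.51 in media to 5.76 ± 0.90 with the cytokines (SD, n = 3 each), where media B and C lay below the background. TBX21, which encodes the Th1 transcription factor T-bet, rose by 0.73 on the log2 scale, with differences of 0.74, 0.73 and 0.72 in pairs A, B and C. IL18RAP, which encodes the accessory chain of the IL-18 receptor, rose by 1.92, with 3.43 in pair A and 1.10 and 1.24 in pairs B and C (1.17 without pair A), and its level in media A lay below the background. The differences of IFNG and IL18RAP are thus taken from media levels that were partly background and are approximate. The chemokine receptor genes CCR8 and CCR7 fell by 1.33 and 0.84, and SPP1, which encodes osteopontin, fell by 1.21. CCR8 lay close to the background in treated A (5.15 against 4.99) and treated C (4.91 against 4.67), so its difference is also approximate.

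These calls came from limma with the letter as a block, with adjusted p-values of 0.0220 for SPP1 and CCR7, 0.0227 for IFNG and CCR8, and 0.0453 for TBX21 and IL18RAP. Each of the 6 genes moved in the same direction in 3 of 3 pairs. Of all 338 tested genes, 127 (37.6%) did so, against 25% expected for random signs. Without the block, limma called 0 of 338 genes (smallest adjusted p 0.528), and 12 genes had an unadjusted p under 0.05, against 51 with the block. Leaving out pair C ended all 6 blocked calls, although the differences stayed at 1.52 for IFNG, 2.265 for IL18RAP, 0.735 for TBX21, −1.215 for SPP1, −0.745 for CCR7 and −1.12 for CCR8, whereas 21 genes, these 6 included, were called without pair A and 21, these 6 included, without pair B. With a pair left out, each gene's own spread is poorly estimated, so these counts lean on the variance that limma shares across genes. Quantile normalization also ended all 6, and housekeeping scaling left 4 calls, 1 higher (IFNG) and 3 lower (CCR7, CCR8 and SPP1), against 3 and 3. The block with no intensity trend left 2 calls, IFNG and SPP1. The block with the stricter floor left 2, CCR7 and SPP1. That floor removed IFNG, CCR8 and IL18RAP before testing, so of the 6 only TBX21 was tested there and not called. Where a gene was tested under settings combined with the block, the smallest differences were 1.12 (IFNG), 1.53 (IL18RAP) and 0.62 (TBX21). For SPP1, CCR7 and CCR8 they were −1.10, −0.80 and −1.11. IFNG exceeded the background in 1 of 3 media samples and IL18RAP in 2 of 3. For genes named below, a difference that moved by over 1.5 times or turned in sign with a sample or pair left out is followed by such values. Leaving out a single sample also breaks its pair, so these values carry differences between letters as well.

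**Figure D1:**
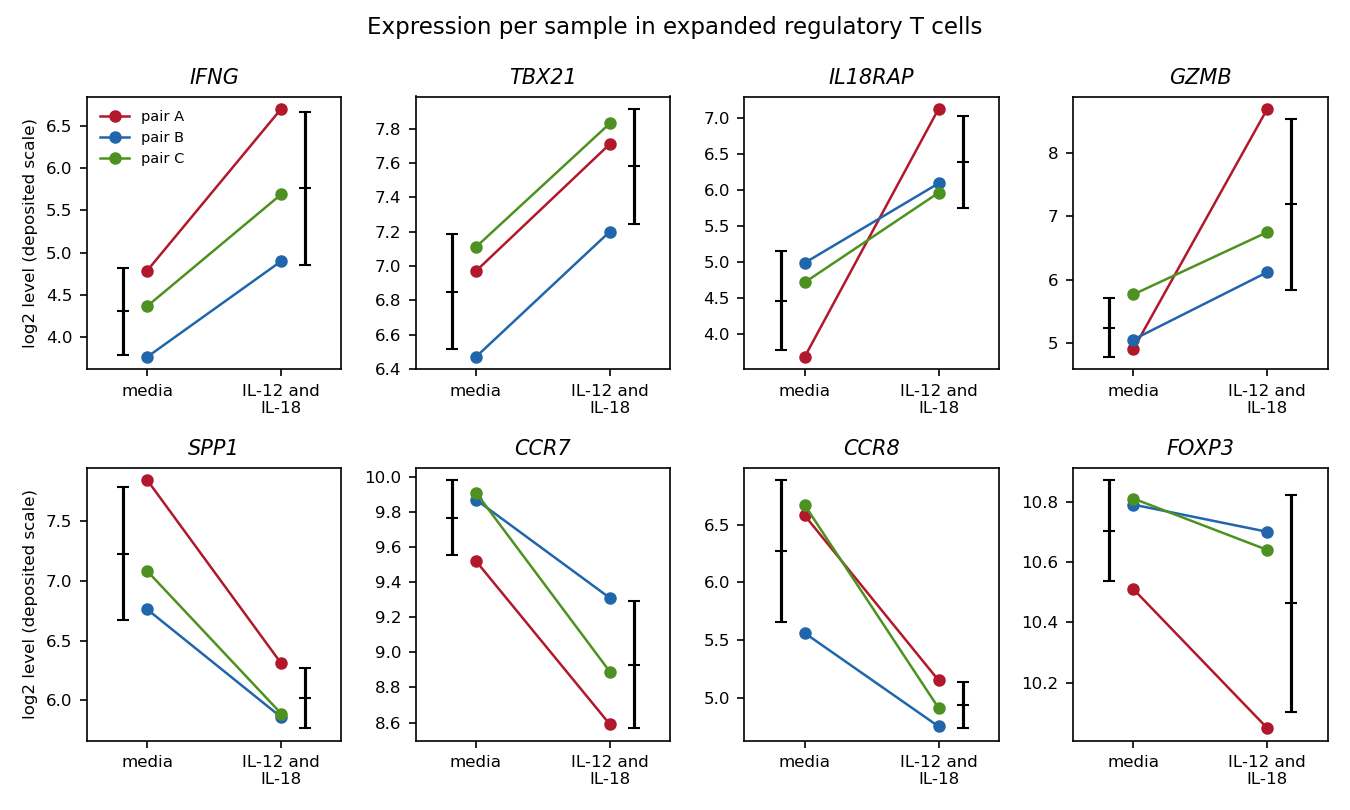
Log2 level on the deposited scale (y axes, which do not start at 0) of 8 genes in media and with IL-12 and IL-18 (x axis); each coloured line joins the samples of one letter, and black marks give the mean and SD of the 3 samples. IFNG, TBX21 and IL18RAP are higher and SPP1, CCR7 and CCR8 lower with the cytokines in 3 of 3 pairs, the GZMB difference is 3.78 in pair A against 1.06 and 0.98 in pairs B and C, and FOXP3 differs by −0.24 on average.

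Among the Th1-associated genes, 9 of 13 tested members were higher in all 3 pairs and 1 was lower in all 3. Adjusted over the list alone, 8 members rose and 1 fell with the block, and 1 member, IL18RAP, rose without it. Over all genes tested, the blocked fit called 3 of them higher and the unblocked fit 0. The risers over the list alone included IFNG, TBX21, IL18RAP, IL18R1 (the ligand-binding chain of the IL-18 receptor, 0.66), CXCR3 (a chemokine receptor of Th1 cells, 0.74), CCL5 (a T-cell chemokine, 1.04) and LTA (lymphotoxin alpha, 0.53). The CCL5 difference was 2.22, 0.39 and 0.50 in pairs A, B and C, and it was 0.31 without the treated sample A and 1.61 without the treated sample C. LTA stood at 0.24 without the treated sample A. TNF stood 0.50 higher and did not pass. The median difference of the list was 0.53 (0.31 without treated A), and camera with a preset correlation of 0.01 placed it above the other genes (adjusted p = 6.59e-05 without the block and 0.000117 with it). With an estimated correlation the call was lost, with an adjusted p of 0.925 without the block and 0.966 with it, and limma's fry gave 0.683 and 0.663. Without the treated sample A, which leaves media A unmatched, the preset camera adjusted p rose to 0.0538. Without the whole pair A, and with the block, it was 5.18e-05. Of 5 measured markers fixed beforehand for conventional CD4 T cells, only CD40LG and IL7R were tested. IL2 (−0.40), IL4 (0.40) and IL17A (0.28) lay below the floor. CD40LG and IL7R were 1.49 higher in the treated sample of pair A, where the Th1 differences were also largest for IFNG, IL18RAP and CCL5. Treated A also had the fewest counts and the highest background (4.99) of the 6 samples.

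Granzyme transcripts, which encode proteases of cytotoxic lymphocytes, were the largest differences in the cytotoxic effector list. GZMB stood 1.94 higher and GZMA 1.78 higher with the cytokines, and both were higher in 3 of 3 pairs. Adjusted over the list of 6 tested members alone, both rose, with the block and without it. Over all genes neither passed, at adjusted p-values from limma with the block of 0.0697 for GZMB and 0.101 for GZMA. Outside the rule, PRF1, which encodes perforin, differed by 0.03 and CTSC by 0.30, and neither passed (values with samples left out are not given for these). The other members named by the rule, TNFSF10 and KLRD1, differed by −0.32 and −0.46 and did not pass. TNFSF10 stood at −0.17 without media A or treated B, −0.51 without media B and −0.55 without treated A. KLRD1 differed by −0.16, −0.48 and −0.73 in pairs A, B and C and, with a single sample left out, stood at 0.00 without media C, −0.02 without treated B, −0.78 without treated C and −0.885 without media B. The size of the granzyme difference rested on pair A, at 3.78 for each gene, against 1.06 and 0.98 for GZMB and 0.56 and 1.00 for GZMA in pairs B and C. Without pair A the differences were 1.02 for GZMB and 0.78 for GZMA, and both genes were called with the block over all genes when pair A, or pair B, was left out. Such fits lean on the variance that limma shares across genes. In pair A, CD40LG and IL7R stood 1.49 higher, and FOXP3 and IKZF2 differed by −0.495 on average, while the Treg identity list had a median of 0.22. The median of the cytotoxic effector list was 0.17 (fry adjusted p 0.922). It stood at −0.015 without pair A, −0.12 without treated A and 0.38 without treated B.

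FOXP3, IL2RA, CTLA4 and IKZF2, genes of Treg identity, had mean log2 levels of 10.03 or higher in both groups. FOXP3, the lineage-defining transcription factor, had a log2 level of 10.70 ± 0.17 in media and 10.46 ± 0.36 with the cytokines, a difference of −0.24 (95% interval −0.53 to 0.05 with the block; −0.03 without treated A). IKZF2, which encodes Helios, differed by −0.23 (−0.05 without treated A) and IL2RA (the IL-2 receptor alpha chain) by −0.36 (−0.225 without pair C). CTLA4 differed by −0.03 (−0.34 without treated A, 0.155 without treated B) and TGFB1 by 0.08 (−0.065 without pair A, 0.17 without pair B), and none of these passed. In pair A, FOXP3 and IKZF2 differed by −0.46 and −0.53, against −0.07 to −0.17 in the other pairs. Of the 13 tested members of the list, 1, CCR8, fell over the list alone and over all genes with the block, and 0 did without it. TNFRSF4, which encodes the costimulatory receptor OX40, stood 0.44 higher (0.22 without treated A) without passing. The list's median difference was −0.03 (−0.20 without media B, 0.11 without pair C), with a fry adjusted p of 0.922. By pair it was 0.22, −0.07 and −0.13 in pairs A, B and C.

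Of 10 tested Tr1-associated genes, 5 were lower and 2 higher in all 3 pairs. Adjusted over the list alone, 1 member, GZMB, rose with the block and 0 changed without it. PRDM1, which encodes the repressor Blimp-1, differed by −0.32 (−0.15 without media A or treated B, −0.58 without treated A). IL10RA differed by −0.38 (−0.19 without treated A, −0.24 without media B, −0.58 without media A). The median difference was −0.05 (−0.14 without treated A, 0.01 without pair C), whereas the mean was 0.15 and fry's direction was upward without the block (adjusted p 0.922) and downward with it (adjusted p 0.940). IL10 was below the background in all 6 samples and was not tested, so a difference in this transcript was not detectable at this depth. ENTPD1 and PDCD1 lay below the floor and were not tested. LAG3, ITGA2, CD226, EOMES, IL12RB2 and HAVCR2 were not analysed here.

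Th2-associated genes gave the single list call by fry without the block. The 4 tested members had a median difference of −0.15 and shifted downward as a set (fry adjusted p 0.0421), a call lost with the block (adjusted p 0.324), under each other scaling, floor and pseudocount set beforehand, and in 5 of 6 fits that left out 1 sample. GATA3, the Th2 master regulator, differed by −0.38, STAT6 by −0.21 (−0.11 without treated A, −0.13 without media C), MAF by −0.08 (−0.003 without media A, −0.13 without media B) and IL4R by 0.07 (−0.11 without treated A, 0.19 without treated C), and 0 of 4 passed over the list alone. With camera the adjusted p was 0.630 at the preset correlation and 0.925 with an estimated correlation. Of the 7 tested Th17-associated genes, 0 passed. IL23R differed by 0.57 (0.33 without treated C, 0.35 without media B), IL1R1 by −0.30 (−0.065 without media C, −0.545 without media B) and CCR6 by 0.35 (0.16 without media A, 0.225 without treated C, 0.61 without media C).

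Of 19 tested interferon response genes, 7 were lower in all 3 pairs and 1 was higher in all 3. Adjusted over the list alone with the block, 7 members fell and 0 rose, and 0 changed without the block or over all genes. STAT2, which encodes a transcription factor of interferon signalling, differed by −0.52. The antiviral gene MX1 differed by −0.73 and IRF1 by −0.50, and all 3 were among the 7 that fell over the list alone. Without pair A these differences were −0.295 for STAT2 and −0.44 for MX1, and without the treated sample B MX1 stood at −1.15. The median difference of the list was −0.54 in pair A, 0.03 in pair B and −0.53 in pair C, and over all pairs −0.31 (−0.185 without pair C, −0.55 without pair B). In pairs A and C the treated sample also had fewer counts than its media partner (373560 against 598825 and 413287 against 586658), and in pair B the totals were 553763 and 556010. Camera with the preset correlation placed the list below the other genes (adjusted p = 2.75e-05 without the block and 3.03e-05 with it). With an estimated correlation the call was lost (adjusted p 0.925 and 0.966), as it was at the preset correlation without the treated sample A (0.151). Without the whole pair A, and with the block, the preset camera adjusted p was 0.0241.

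**Figure D2:**
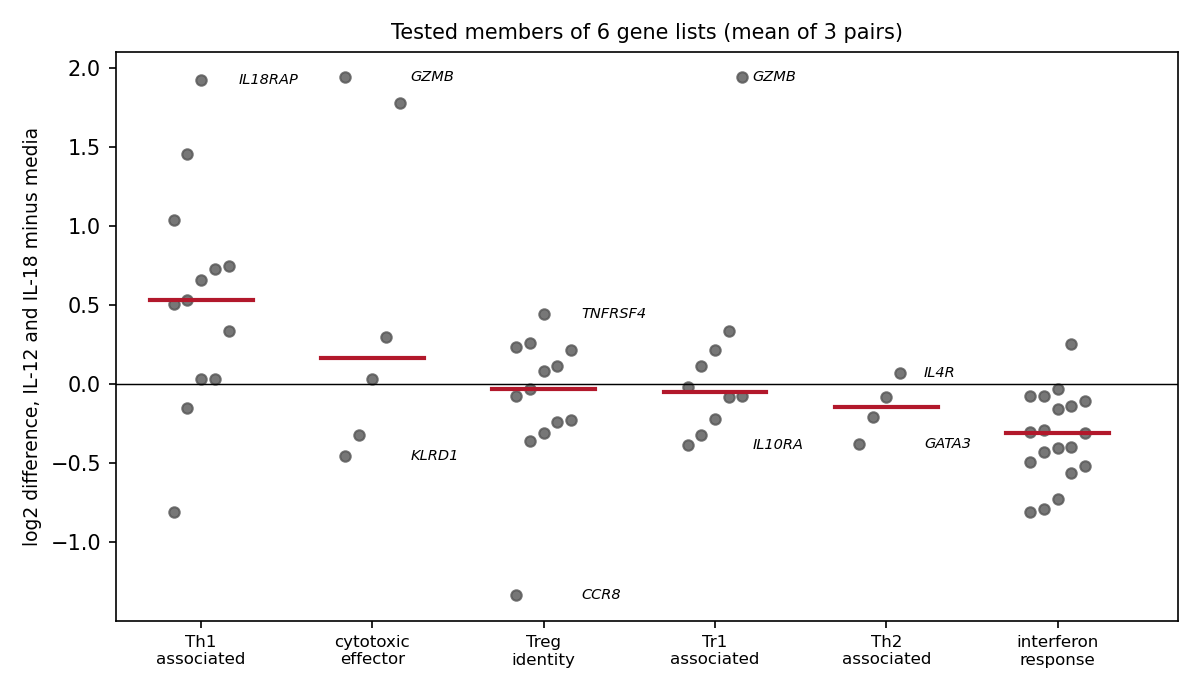
Log2 difference between IL-12 and IL-18 and media, as the mean of 3 pairs (y axis), for each tested member of 6 gene lists (x axis); points are genes, offset sideways only for legibility, red bars are list medians, and the highest or lowest gene of a list is labelled where the text names it. The Th1-associated median is 0.53 and the interferon response median −0.31, while the Treg identity and Tr1-associated medians lie at −0.03 and −0.05.

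In the list of receptor signalling for IL-12, IL-18 and IL-2, IL18RAP and IL18R1 rose and JAK2 fell (by 0.51) over the list alone with the block, out of 18 tested members (JAK2 stood at −0.33 without the treated sample A). The median of this list was −0.005 and the mean 0.075, with fry upward without the block (adjusted p 0.922) and downward with it (adjusted p 0.940). IL12RB1, a chain of the IL-12 receptor, differed by 0.03 (−0.23 without treated A, 0.24 without treated B) and STAT4, its downstream transcription factor, by −0.15 (−0.02 without treated B, −0.28 without treated A). Neither passed, and the sign for IL12RB1 also turned under housekeeping scaling (−0.07) and median centring (−0.05). Among 20 homing and adhesion receptors, 3 rose and 2 fell over the list alone with the block. CXCR3 and the integrin gene ITGA6 (0.62, and 0.335 without pair A) were among the risers, and CCR7 and CCR8 were the genes that fell. In the quiescence list CCR7 and IL6R (−0.63, and −0.31 without media C) fell over the list alone with the block, out of 10 tested members, while IL7R stood at 0.52 (0.03 without pair A, 0.88 without pair B) and BCL6 at 0.36 (0.19 without media A, 0.195 without pair A) without passing. CD274, which encodes the ligand PD-L1, was 0.72 higher and was the 1 of 7 coinhibitory genes that rose over the list alone with the block. CD96 and TIGIT differed by 0.43 (0.20 without treated A) and −0.08 (−0.005 without media A, −0.16 without treated A) without passing. With the block, fry's test for change in either direction passed for this list (adjusted p 0.00448), and without it the value was 0.829. Of 10 tested T-cell cytokines and chemokines, IFNG, LTA and CCL5 rose over the list alone with the block.

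No member passed over the list alone, with or without the block, in 6 further lists. Costimulatory genes (13 tested) included CD40LG at 0.70 (0.15 without treated A, 1.09 without treated B), TNFRSF8 at 0.54 (0.17 without treated A, 0.95 without treated B) and CD2 at −0.23 (−0.09 without media C, −0.04 without pair C), with a list median of −0.10, a mean of 0.04 and fry upward (adjusted p 0.960). NF-kappaB and TNF signalling (22 tested) included NFKBIA at −0.54 (−0.335 without pair C), IKBKE at −0.39 (−0.24 without treated A, −0.26 without media B) and TNFAIP3 at −0.32 (−0.205 without pair C), all lower in 3 of 3 pairs. T-cell receptor signalling (22 tested) included DPP4 at 0.37, CD6 at −0.33 (−0.15 without media C), FYN at −0.30 (−0.095 without media B, −0.10 without treated A, −0.46 without treated B, −0.575 without media A) and CD247 at −0.29. Antigen processing and HLA genes (22 tested) included TAP1 at −0.43 (−0.24 without media A), TAP2 at −0.29 (−0.13 without treated A, −0.18 without treated C, −0.58 without treated B) and HLA-C at −0.37 (−0.205 without treated C), whose probe can share signal with related genes. Apoptosis and survival (13 tested) included FAS at −0.49 (−0.29 without media C, −0.785 without media B) and CASP2 at 0.21 (0.07 without media A, 0.32 without media B). TGF-beta signalling had 6 tested members.

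Markers of other cell types were mostly near or below the floor. CD8A and CD8B, which mark CD8 T cells, were both untested, at mean log2 levels of 4.35 and 4.01 in media and 4.19 and 4.12 with the cytokines. Of the measured NK-cell markers 5 of 11 were tested, with the highest levels in FCGR3A (5.56 in media) and KLRD1 (5.05), which differed by −0.40 (−0.08 without pair A, −0.675 without pair B) and −0.46 (0.00 without media C, −0.885 without media B). Of the B-cell markers 3 of 12 were tested, led by CD79A at 6.53 in media, and of the granulocyte markers 2 of 5, led by CEACAM1 at 8.92. Of the myeloid markers 7 of 29 were tested, with ITGAM at 10.89, CD80 at 9.16 and FCER1G at 8.91 in media, genes that activated lymphocytes can also express. Of these 7 markers, 4 were higher and 1 lower in all 3 pairs, and ITGAX differed by 0.64 (0.30 without pair A). None of these passed over its list alone. Of the conventional CD4 T-cell markers, 2 of 5 were tested, and CD40LG rose over that list alone with the block, at 0.15 without treated A and 1.09 without treated B. The mean level of 15 housekeeping genes was 9.23 ± 0.15 in media and 9.33 ± 0.13 with the cytokines (SD, n = 3 each), and it was higher with the cytokines in 3 of 3 pairs, by 0.10, 0.05 and 0.18 in pairs A, B and C. A two-sided exact test that flips signs within pairs gave p = 0.25, the smallest value that 3 pairs allow, and the unpaired exact permutation test gave p = 0.5, where 0.1 is the smallest.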

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

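The random block, the floor from the negative controls, the settings combined with the block and the camera values under other settings were chosen after seeing the data. The unblocked fit called 0 genes under every alternative without a block (housekeeping scaling, median centring, quantile normalization, no floor, the stricter floor, the negative-control floor, a pseudocount of 10, no intensity trend, sample weights), except that 1 gene, IL18RAP, was called higher without media B. With the letter as a fixed block 6 genes were called, 3 higher and 3 lower, and with the letter as a random block 11 were called, 7 higher and 4 lower. Leaving out samples or pairs gave between 0 and 21 changed genes, 0 to 11 higher and 0 to 13 lower. The lower residual spread with the block accompanied these calls. A test with edgeR was planned for whole counts only and was not run, because the values are on a log2 scale. The pairing changed no other call than those in the report.

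The blocked count of 6 became 17 with median centring, 9 with sample weights, 7 with no floor, 4 with housekeeping scaling, 2 with the stricter floor (264 genes tested), 2 with no intensity trend and 0 with quantile normalization. The stricter floor removed IFNG, CCR8 and IL18RAP before testing. Leaving out a pair gave 0 (without C) to 21 (without A, and without B), in fits that lean on the variance that limma shares across genes. Housekeeping scaling moved the median difference of all genes from 0.003 to −0.105, so that rises are smaller and falls larger by this amount. The cause of the other changes was not tested.

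The number of lists shifted in one direction, 1, fell to 0 with the block, housekeeping scaling, median centring, quantile normalization, no floor, the stricter floor and a pseudocount of 10. That call was of the Th2-associated list with fry. Camera, a test of another form, called 2 other lists (Th1-associated and interferon response) at the preset correlation and 0 with an estimated one. Leaving out a sample or pair gave 0 or 1. The preset camera p of the interferon response list ranged from 8.4e-10 (without treated B) to 0.151 (without treated A), and that of the Th1-associated list from 1.56e-05 (without treated C) to 0.0538 (without treated A). Without the whole pair A, and with the block, the values were 0.0241 and 5.18e-05.

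Of 70 tested genes named in the text and run under the alternatives, 61 kept the sign of their difference in every alternative run for them. Of the others, 1 (KLRD1) stood at 0 without media C, and 8, each close to 0 or varying between pairs, turned in at least 1. None of the 8 was called over all genes. Quantile normalization gave 0.049 for CTLA4 and also for the Treg identity median. Housekeeping scaling gave −0.028 for TGFB1, −0.075 for IL12RB1, −0.042 for IL4R, −0.015 for ITGAM and −0.012 for CEACAM1. Median centring gave −0.045 for IL12RB1 and −0.012 for IL4R, and sample weights gave −0.158 and −0.053. With samples or pairs left out, values ran from −0.340 to 0.155 for CTLA4, −0.065 to 0.170 for TGFB1, −0.232 to 0.238 for IL12RB1, −0.112 to 0.193 for IL4R, −0.752 to 0.193 for CD79A, −0.097 to 0.315 for ITGAM, −0.023 to 0.227 for CEACAM1 and −0.168 to 0.010 for SOCS1. List medians ran from −0.197 to 0.110 for Treg identity, −0.139 to 0.010 for Tr1-associated and −0.118 to 0.378 for cytotoxic effector genes. Signal over background limits what can be seen of low genes, most of all in treated sample A, where the background reached 4.99.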

Other observations

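The tests of explanations and the counts over other splits were chosen after the results were seen, as were the genes and gene groups of the next paragraph.

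Antigen presentation genes were also looked at in 3 groups, whose differences from one another were not tested. The 8 tested class II genes had a median difference of 0.13 between IL-12 and IL-18 and media, from 0.01 to 0.39, and 2 of them were higher and 0 lower in all 3 pairs. The highest, HLA-DRA, differed by 0.50, 0.43 and 0.25 in pairs A, B and C; with a single sample left out, which breaks its pair, it stood between 0.04 (without media B) and 0.73 (without treated B). TAP1, TAP2 and TAPBP, genes of the class I peptide pathway, had a median of −0.29. Of these 3 genes 2 were lower in all 3 pairs. The 3 immunoproteasome genes had a median of −0.11, and 0 of them were lower in all 3 pairs. Probes of related HLA genes can share signal, and no HLA gene passed over all genes. CXCR6, a homing receptor of effector T cells, stood 0.95 higher. ITGAX, an integrin gene from the list of myeloid markers, stood 0.64 higher. PTGER4, a prostaglandin E2 receptor gene, differed by −0.47 and the transcription factor gene POU2F2 by −0.52. CXCR6 stood at 0.40 without the treated sample A and ITGAX at 0.30 without pair A, without media C PTGER4 stood at −0.27 and POU2F2 at −0.34, and without the treated sample B PTGER4 stood at −0.28. Each held its direction in 3 of 3 pairs, as did 37.6% of all tested genes, and none passed with the block over all genes.

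The first pattern is lower values of interferon response genes beside higher IFNG, with list medians of −0.54, 0.03 and −0.53 in pairs A, B and C and 7 of 19 genes lower in all 3 pairs. As a shift of the list it is not established, with a camera adjusted p = 0.925 with an estimated correlation (0.966 with the block) and a fry adjusted p of 0.922. One scaling or depth factor per sample, which would move genes of like level alike, is argued against by the list median of −0.31 in these samples, at percentile 0.02 of 10000 lists matched on level (their median −0.05; correlation between members is ignored), but RNA quality and other differences that go with the lower counts of treated A and C were not tested and stay open. A negative-feedback hypothesis, higher SOCS1 (an inhibitor of interferon signalling) at harvest, stays open, since SOCS1 differed by −0.073 with a 95% interval of −0.36 to 0.21 (−0.17 without treated B, 0.01 without pair C). The design names the added cytokines, whose part in this pattern was not tested beyond the comparison itself.

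The second pattern is the granzyme difference, 1.86 on average for GZMA and GZMB. CD8 T cells or NK cells in the treated cultures are a candidate source, although the sort on CD4 would remove most of them. The 8 CD8 and NK markers above background in at least 3 samples differed by 0.005 on average (SD 0.36). As a mean of 3 pairs, the highest was 0.59. In pair A, where the granzymes differed by 3.78, the markers differed by 0.24 on average. They ran there from −1.04 (FCGR3A) to 1.41 (KIR3DL1), with NCAM1 at 0.80. These markers lay only 0.18 above background on the log2 scale, so a small share of such cells rich in granzymes cannot be told apart from a rise within Tregs. In the same pair A, CD40LG and IL7R (markers of conventional CD4 T cells) differed by 1.49, and FOXP3 and IKZF2 by −0.495 on average. The Treg identity list had a median of 0.22 in that pair.

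The third pattern is the larger response of pair A, where 26 tested genes differed by over 1 on the log2 scale, against 5 in pair B and 8 in pair C. Treated A had the fewest counts (373560), the highest background (4.99) and the lowest sample weight (0.418); among 267 genes above 4.99 in all 6 samples, 13 differed by over 1 in pair A, against 0 and 3, which argues against noise near the background for these 13 and leaves it open for the other 13, such as FCGR3A. A larger share of conventional CD4 T cells in the treated sample of pair A may contribute. FOXP3 and IKZF2 differed there by −0.495 on average, against −0.08 and −0.125 in pairs B and C. CD40LG and IL7R differed by 1.49, against 0.035 and 0.305. The median of the 13 tested Treg identity genes went the other way, at 0.22 in pair A against −0.07 and −0.13. The sort on low CD127, the product of IL7R, was made before expansion. The gate of the sort before RNA extraction is not given in the sources used here. A stronger action of the cytokines on the Tregs of this pair would give the same values. The case for conventional CD4 T cells is thus mixed and rests on 1 sample. All 6 blocked calls were also made without pair A, but that fit leans on the variance that limma shares across genes. The 6 differences kept their direction there, from 0.725 (TBX21) to 1.225 (IFNG) for the rises and from −0.79 (CCR7) to −1.285 (CCR8) for the falls.

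Splits of the samples were counted for the calls. Without the block the real count was 0 genes, which each of the 10 splits of the 6 samples reaches by necessity, so this count decides nothing. The highest other count was 1. For lists, 2 of 10 splits gave as many as the real 1, with a highest other count of 1. With the block, 1 of the 4 splits that part all 3 pairs, the real one, gave 6 genes, and the highest other gave 0. The 6 splits that part a single pair gave up to 4. Without the block, a split that keeps letters A and B whole gave 88 genes at an unadjusted p under 0.05, against 12 for the real split, which points to differences between the letters. With 10 or 4 splits a share under 0.05 cannot be reached.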
